A study of Mus musculus with 83 samples.

How the data were processed

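RNA was measured in single ovarian follicles of CD-1 mice, an outbred strain. Per the labels' protocols, follicles were used fresh or after vitrification, a form of cryopreservation in which cells are cooled into a glass without ice crystals. Both kinds were cultured for 8 days in beads of 0.5% alginate. Follicles of 300 to 350 µm were then freed from the beads and moved to a maturation medium with 1.5 IU/ml human chorionic gonadotropin (hCG, which acts on the receptor for luteinizing hormone), 10 ng/ml EGF and 10 mIU/ml recombinant FSH. Collection followed 0, 1, 4 or 8 h later. Each library came from 1 follicle, with cDNA made by Smart-Seq2, a full-length protocol without molecular identifiers, and paired-end libraries made by Nextera XT, a kit that does not mark strand.

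The authors deposited 2 tables for the same 83 libraries, each with 21572 gene rows. The first held estimated counts per gene, which were not whole numbers, per the values in the deposited table. The second held the authors' log2(TPM + 1) values. Partek, Bowtie2, HISAT2, DESeq2 and build mm10 are named in the submitters' processing notes, without versions or roles, and how reads that match several genes were counted is not given in the sources used here. Of 21571 different symbols, 21109 (97.9%) matched a gene of GENCODE vM21, the annotation used here for positions on GRCm38, and 21070 matched exactly 1. Symbols of 21 rows looked like dates; these rows stayed in the tests and are not named. Values of 2 further genes are not reported here, though counts include them. None of the 13 mitochondrially encoded genes was listed under its name. A BLAST search at 90% identity over 90% of the transcript found 15 nuclear gene models that resemble mitochondrial transcripts, and their summed share of counts was used as a substitute, chosen after seeing the data.

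Groups were fresh or vitrified follicles at each of the 4 times, 8 groups in all. Library titles name 3 plates. The first held all and only the 0 h libraries, so that the step from 0 h to 1 h cannot be separated from a difference between plates. The second, called the shared plate here, held the fresh libraries of 1, 4 and 8 h, with 5, 7 and 3 vitrified libraries of these times. The third, called the vitrified-only plate here, held 9 vitrified libraries of 1 h and 9 of 8 h. Each group also had plate rows of its own. Within the shared plate, 3 of the sample numbers that end the titles occur both for fresh 4 h and fresh 8 h libraries, and 4 both for fresh 1 h and vitrified 1 h libraries. These rows may therefore come from different runs, which the labels do not name, and comparisons within the shared plate can still hold such a difference. The labels give neither animals nor culture runs, so p-values measure the spread between follicles, which may be partly technical.

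Estimated counts were rounded to whole numbers and tested with edgeR's quasi-likelihood test (robust fit). Scaling was by TMM, and genes were kept by edgeR's expression filter with a minimum count of 10, which left 11521 genes. One model held all 83 libraries, with a mean for each group and 1 term for the vitrified-only plate. That term takes the plate difference to be the same at 1 h and 8 h, which did not hold: among vitrified follicles 1 gene of 6904 was called between plates at 1 h and 2725 of 10163 at 8 h. The comparisons were vitrified minus fresh at each time, each step between neighbouring times in fresh and in vitrified follicles, and the difference between the vitrified and the fresh step, 13 in all. P-values were adjusted by Benjamini-Hochberg within each comparison and read at 0.05. Counts of genes at an unadjusted p under 0.05 are given beside some results. About 1 in 20 of the genes tested would reach it by chance alone. Standard errors (SE) of log2 fold changes were derived from the F statistic. Fixed gene lists were tested with camera at a preset correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over 260 tests. Of these, 71 passed, and 37 passed when the correlation was estimated. Shares of genes have exact Clopper-Pearson 95% intervals, which cover counting error only. Library makeup was compared by two-sided permutation tests, exact where a group had fewer than 10 libraries and otherwise with 100000 resamples. PERMANOVA (adonis2 of vegan, 10000 permutations) used the 500 most variable genes in the 32 libraries of the shared plate.

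The lists were immediate early genes, EGF-like factors and early targets of luteinizing hormone, cumulus expansion and matrix, ovulatory transcription factors and effectors, proteases and inhibitors, progesterone synthesis, estradiol synthesis and FSH-dependent granulosa genes, cumulus and preantral granulosa genes, cholesterol synthesis, glycolysis and hypoxia, proliferation, inflammatory genes, heat shock, p53 targets and apoptosis, endoplasmic reticulum stress, oxidative stress, mitochondrially encoded genes, and markers of oocyte, theca and stroma, granulosa, immune, endothelial and erythroid cells. Named genes are up to 4 members per list with the smallest adjusted p. To these were added the 10 largest increases and the 10 largest decreases among called genes with a median of at least 10 CPM in the higher group, predicted gene models left out. The lists, this rule, the model and the alternatives were fixed before the data were examined. Added alternatives were chosen after seeing the data: scaling by total counts alone, leaving out libraries under 1500000 counts, and merging vitrified 4 h replicates 1 and 2.

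The alternatives fixed in advance were DESeq2 size factors, no low-count filter, the DESeq2 Wald test, no plate term, leaving out the vitrified-only plate, limma-trend on the deposited log2(TPM + 1) values for genes with a mean of at least 1, leaving out each fresh 8 h replicate, fitting only the compared groups, and an estimated correlation for camera. A filter fixed in advance at 500000 counts and 6000 genes removed 0 libraries and was void. Vitrified 4 h replicates 1 and 2 had a chi-square of 1.97 per gene, against 4.01 to 16.43 for the closest pair in the other groups. A pair of libraries from 1 follicle could also exceed sampling noise, so it stays open whether they are separate follicles. Both were kept, and the count of 7 vitrified libraries at 4 h includes both.

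TMM factors averaged 1.20 and 1.10 at 0 h, 0.856 and 0.720 at 1 h, 0.854 and 0.817 at 4 h, and 1.33 and 1.23 at 8 h in fresh and vitrified follicles. With total counts alone the median log2 fold change of all genes moved from -0.11 to -0.59 in the fresh and from -0.05 to -0.66 in the vitrified step from 0 h to 1 h. It moved from 0.12 to 0.75 and from 0.21 to 0.80 in the fresh and vitrified steps from 4 h to 8 h, and from -0.09 to 0.07 in the vitrified step from 1 h to 4 h. For vitrified minus fresh it moved from -0.02 to -0.13 at 0 h, from 0.06 to -0.19 at 1 h and from 0.11 to 0.00 at 8 h.

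The procedure was tested on simulated data drawn from the means and library sizes of the real genes, with 200 of 11521 genes changed. Recovered were 32.8%, 68.7% and 92.4% of genes changed 1.5-fold, 2-fold and 4-fold for vitrified minus fresh at 0 h. The corresponding shares were 5.97%, 41.8% and 75.8% at 1 h, 1.49%, 31.3% and 69.7% at 4 h, and 4.48%, 22.4% and 65.2% at 8 h. For the fresh steps they were 14.9%, 47.8% and 80.3% from 0 h to 1 h, 4.48%, 37.3% and 80.3% from 1 h to 4 h, and 1.49%, 20.9% and 66.7% from 4 h to 8 h. For the vitrified steps they were 11.9%, 38.8% and 84.9%, then 7.46%, 34.3% and 75.8%, then 5.97%, 29.9% and 80.3%. For the differences between steps they were 4.48%, 19.4% and 57.6%, then 1.49%, 8.96% and 48.5%, then 0%, 10.5% and 62.1%. Between 1 and 9 unchanged genes were called in each simulation, the highest being 9 of 81 calls for vitrified minus fresh at 4 h. The simulated libraries held no difference between plates, so these shares do not test the plate term used at 1 h and 8 h. Tools were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, vegan 2.7.1, BLAST 2.17.0, Python 3.11.15 and matplotlib 3.10.9.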

Results

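Transcriptomes of 83 single mouse ovarian follicles were compared to ask whether vitrification alters the response to an ovulatory stimulus in culture. Fresh follicles numbered 18, 6, 7 and 4 at 0, 1, 4 and 8 h after hCG, and vitrified follicles 15, 14, 7 and 12. Total counts per library ranged from 682200 to 6504588, and the library with the fewest detected genes still had a count in 11830. Group means of total counts lay between 2281000 ± 483420 (SD, n = 7, fresh 4 h) and 3974100 ± 1973200 (n = 4, fresh 8 h). Adjusted p-values for single genes are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and those for gene lists are from camera.

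Granulosa cell genes made up the largest share of any marker list, 9.42% ± 1.20 of counts in fresh follicles at 0 h (SD, n = 18) and 9.77% ± 0.917 in vitrified follicles (n = 15). Oocyte markers took 0.0610% ± 0.0118 and 0.0647% ± 0.0225 at 0 h, a difference within the spread between follicles (permutation test, adjusted p = 0.82). The 50 most abundant genes held 42.2% ± 1.71 of counts in fresh (n = 6) and 46.0% ± 2.41 in vitrified follicles (n = 14) at 1 h (exact permutation test, adjusted p = 0.0341). Within the shared plate that difference was 2.71 percentage points (exact permutation test, adjusted p = 0.26). Total counts at 1 h differed within the shared plate, 2596800 ± 469860 (n = 6) in fresh against 4609300 ± 970630 (n = 5) in vitrified follicles (exact permutation test, adjusted p = 0.0341). Over all plates the 1 h difference in total counts was 570660 (adjusted p = 0.705, exact permutation test). Nuclear gene models resembling mitochondrial transcripts held 4.15% ± 0.546 (n = 18) and 4.45% ± 0.746 (n = 15) of counts at 0 h in fresh and vitrified follicles (permutation test, adjusted p = 0.588).

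Time after hCG separated the follicles along both leading principal components, which carried 58.7% and 24.1% of the variance. Within the shared plate, time accounted for 79.8% of the variance of the 500 most variable genes (permutation test on distances, p = 1e-04, the smallest the permutations can give). Vitrification accounted for 2.06% (p = 0.0448 by permutation). Those 500 genes were chosen for their variance in the same libraries. Over all genes tested the share of time was 55.7% and that of vitrification 2.42% (p = 0.113 by permutation).

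**Figure D1:**
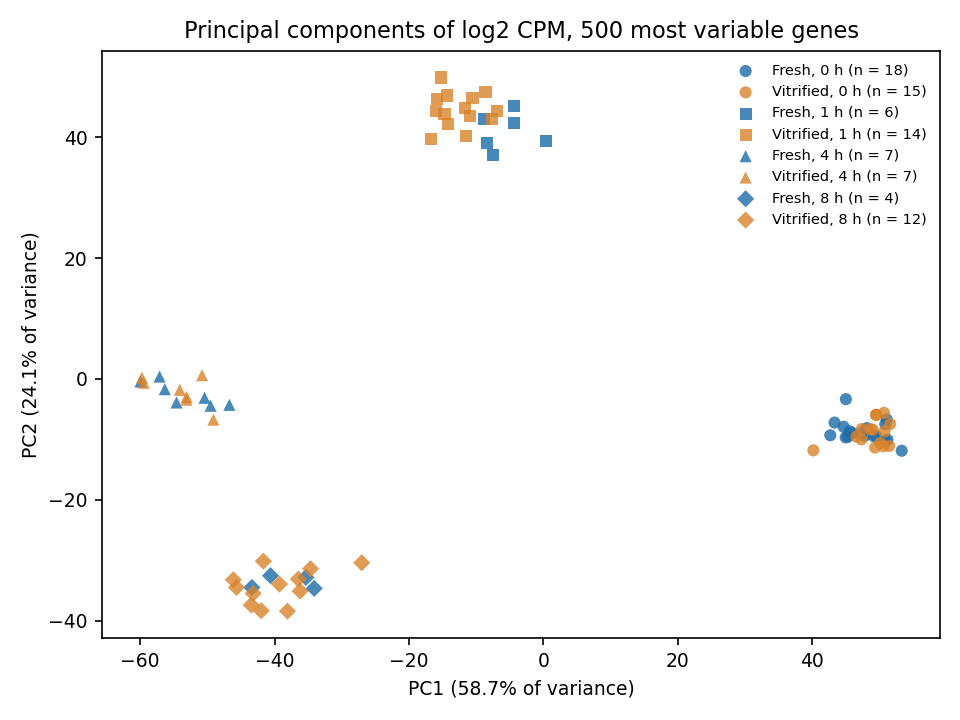
Principal components of log2 CPM of the 500 most variable genes, PC1 (58.7% of variance) on the x axis and PC2 (24.1%) on the y axis, each point 1 follicle, with colour for fresh or vitrified and shape for time. The follicles of 0 h lie at the right, those of 4 h at the left, those of 1 h at the top and those of 8 h at the bottom, with fresh and vitrified points of one time side by side.

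The first step asked what changed in fresh follicles within 1 h of hCG. Areg and Ereg, EGF-like growth factors that relay the signal of luteinizing hormone inside the follicle, went from near 0 to among the more abundant transcripts. Areg rose from 0.381 ± 0.414 CPM (SD, n = 18) to 733 ± 188 CPM (n = 6), a log2 fold change of 10.72 ± 0.39 (SE; edgeR adjusted p = 6.88e-39), and Ereg by 12.55 ± 0.45 on the same scale. Star, which moves cholesterol into mitochondria for steroid synthesis, rose from 10.1 ± 9.43 to 13000 ± 4310 CPM (log2 fold change 10.35 ± 0.49), and Pgr, the progesterone receptor, from 2.85 ± 2.63 to 1880 ± 549 CPM (9.25 ± 0.40). Ptgs2, the inducible prostaglandin synthase, rose by 10.65 ± 0.38, and the orphan nuclear receptors Nr4a3 and Nr4a2 by 13.09 ± 0.41 and 11.73 ± 0.37. Among the decreases, Txnip, an inhibitor of thioredoxin, changed by -5.81 ± 0.46, Kctd14 by -4.92 ± 0.57 and the clock repressor Nr1d1 by -3.75 ± 0.37. In total 2199 genes rose and 2679 fell of 11521 tested.

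Of 24 immediate early genes 22 rose and none fell in fresh follicles (camera adjusted p = 2.85e-26), among them Ier3 (log2 fold change 6.69 ± 0.28) and Klf4 (6.85 ± 0.34). Of 15 EGF-like factors and early targets of luteinizing hormone, 13 rose (4.24e-26 by camera), with Crem at 8.36 ± 0.27 and Rgs2 at 5.77 ± 0.20. The cumulus expansion list, 8 higher and 1 lower of 11, included Tnfaip6 and Has2, which bind and make hyaluronan (8.22 ± 0.39 and 5.33 ± 0.47; camera adjusted p = 3.31e-05). Ovulatory transcription factors and effectors went up in 8 and down in 1 of 15 (5.2e-05), with Rgcc at 6.01 ± 0.28 and Runx1 at 4.65 ± 0.40. Of 16 proteases and inhibitors 10 rose and none fell (5.72e-05), led by Adamts1 at 4.52 ± 0.18 and the plasminogen activator Plau at 4.51 ± 0.32. Cholesterol synthesis had 11 higher and 2 lower members of 20 (camera adjusted p = 0.00324, and adjusted p = 0.665 with an estimated correlation), for example Cyp51 at 2.60 ± 0.21 and Insig1, which restrains the pathway, at 2.41 ± 0.17. Progesterone synthesis had 7 higher and 2 lower of 15 (camera adjusted p = 0.0163, and adjusted p = 0.318 with an estimated correlation), with Fdx1 at 5.01 ± 0.21 and the steroidogenic regulator Nr5a1 at -2.36 ± 0.20. That list lay above 0 in the median with TMM and below 0 with total counts alone.

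Stress lists moved in the same hour in fresh follicles. Of 15 heat shock genes 12 rose and none fell (camera adjusted p = 9.03e-08), with the co-chaperone Bag3 at 3.80 ± 0.14. Endoplasmic reticulum stress genes rose in 10 of 15 (9.03e-08), with Dnajb9 at 3.43 ± 0.17 and Atf4 at 2.81 ± 0.14. Of 16 p53 targets 8 rose and 2 fell (0.00506), with Gadd45b at 8.81 ± 0.34 and the cell cycle inhibitor Cdkn1a at 4.33 ± 0.24. Of 17 oxidative stress genes 8 rose and 2 fell (camera adjusted p = 0.0388, and adjusted p = 0.302 with an estimated correlation), with the sulfiredoxin Srxn1 at 8.87 ± 0.33, and the median of this list turned from 0.37 to -0.12 with total counts alone. Estradiol synthesis and FSH-dependent genes divided, 3 higher and 4 lower of 17 (0.915): Cyp19a1, the aromatase, rose by 3.58 ± 0.25 and the ovarian transcription factor Foxl2 changed by -3.25 ± 0.38. Other lists that did not pass camera were cumulus and preantral granulosa genes (3 higher of 12, adjusted p = 0.388), glycolysis and hypoxia (2 higher and 4 lower of 18, 0.828), proliferation (1 higher and 3 lower of 19, 0.863) and inflammatory genes (6 higher and 1 lower of 7, 0.0651). Markers of other cells did not pass either: oocyte (1 higher of 18, 0.65), theca and stroma (1 higher and 1 lower of 14, 0.771), granulosa (2 higher and 3 lower of 11, 0.788) and endothelial (4 higher of 6, 0.497). The 1 immune marker tested, Lyz2, had a log2 fold change of 0.38 ± 0.79, and no erythroid or mitochondrially encoded gene was tested.

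Adjusted over the list alone, these fresh counts were the same except for 9 higher ovulatory transcription factors, 9 higher p53 targets, 11 higher endoplasmic reticulum stress genes, 3 higher granulosa markers, 5 higher endothelial markers and 1 lower proliferation gene. The step is confounded with the plate, since all 0 h libraries shared a plate of their own. With total counts alone the division was 1139 higher and 5129 lower.

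Vitrified follicles over the same hour raised Nr4a3 (log2 fold change 14.63 ± 0.50), Ereg (12.57 ± 0.48), Areg (12.33 ± 0.46; edgeR adjusted p = 4.08e-38) and Pgr (11.88 ± 0.50). Mean Areg went from 0.177 ± 0.288 CPM (n = 15) to 1460 ± 534 CPM (n = 14), Star from 43.8 ± 36.3 to 17000 ± 6120 CPM and Ptgs2 from 0.0479 ± 0.103 to 165 ± 64.5 CPM. The kinase Sik1 rose by 11.60 ± 0.43 and the tissue factor gene F3 by 11.52 ± 0.35, while Kctd14 and Txnip changed by -5.33 ± 0.58 and -4.96 ± 0.41. In all, 2761 genes rose and 2988 fell (total counts alone: 1302 and 5704).

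Immediate early genes rose in 23 of 24 in vitrified follicles (camera adjusted p = 6.19e-22), the EGF-like list in 13 of 15 (1.48e-21), cumulus expansion in 7 of 11 with 1 lower (0.000129), ovulatory transcription factors in 8 of 15 (0.000362), and proteases in 11 of 16 (1.64e-05). Heat shock genes rose in 11 of 15 (4.01e-07), with Bag3 at 4.44 ± 0.15, and endoplasmic reticulum stress genes in 11 of 15 (9.61e-07). Cholesterol synthesis had 12 higher and 2 lower of 20 (0.0129, adjusted p = 0.774 with an estimated correlation), progesterone synthesis 8 and 3 of 15 (0.0309, adjusted p = 0.423 with an estimated correlation), and oxidative stress 12 and 1 of 17 (0.0137, adjusted p = 0.208 with an estimated correlation). Of 16 p53 targets 8 rose and 2 fell (0.0356, adjusted p = 0.101 with an estimated correlation), and the median of that list turned from 0.39 to -0.21 with total counts alone. Estradiol synthesis had 7 higher and 4 lower of 17 (0.842), cumulus and preantral genes 5 higher of 12 (0.376), and theca and stroma markers 4 higher and 1 lower of 14 (0.649). Adjusted over the list alone, these counts were the same except for 9 higher ovulatory transcription factors, 2 lower oxidative stress genes and 5 lower estradiol genes.

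Of the 4878 genes called in fresh follicles, 98.7% (95% interval 98.3 to 99.0) moved in the same direction in vitrified follicles. Higher in both were 1924 genes, where independent lists would share 527, and lower in both were 2183, against 694.8; 3 genes called in both went opposite ways. Log2 fold changes correlated across genes at Pearson r = 0.908 and Spearman rho = 0.867, a description, since genes are not independent replicates. A difference between the 0 h plate and the others enters both steps, and may raise the share, the overlap and the correlation. The steps themselves differed in 3 genes (2 higher and 1 lower, of 861 with an unadjusted p under 0.05). Hnrnpu, a nuclear RNA-binding protein, rose by 3.46 in vitrified and had a log2 fold change of 0.61 in fresh follicles (difference 2.85 ± 0.58, edgeR adjusted p = 0.0282). Fam222b had steps of -2.43 in fresh and -0.84 in vitrified follicles (difference 1.59 ± 0.27, 0.000899). Nfkbia, the inhibitor of NF-kB, had steps of -0.56 and -1.81 (difference -1.25 ± 0.26, 0.0343). Without the vitrified-only plate the adjusted p-values were 0.0106, 0.0191 and 0.0191. Without a plate term only Nfkbia of the 3 was called (21 genes in all), with no low-count filter Hnrnpu and Fam222b, in a fit of the compared groups Hnrnpu and Nfkbia, and with limma none. In fits of the compared groups only, the real split called 4 genes and random splits up to 64, and 4 of 50 splits called as many. Chance was not excluded for the count of that fit. The splits did not test the 3 calls of the main model, for which chance stays open. By list, inflammatory genes were lower in this difference (camera adjusted p = 0.00144), and proteases (0.0456, adjusted p = 0.426 with an estimated correlation) and glycolysis (0.0494, adjusted p = 0.843 with an estimated correlation) higher, with Nfkbia the only member called by edgeR. Only 7 of the 21 genes of the inflammatory list were tested. The adjusted p of inflammatory genes was 0.00247 without the vitrified-only plate and that of proteases 0.11, and glycolysis turned lower (0.898).

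**Figure D2:**
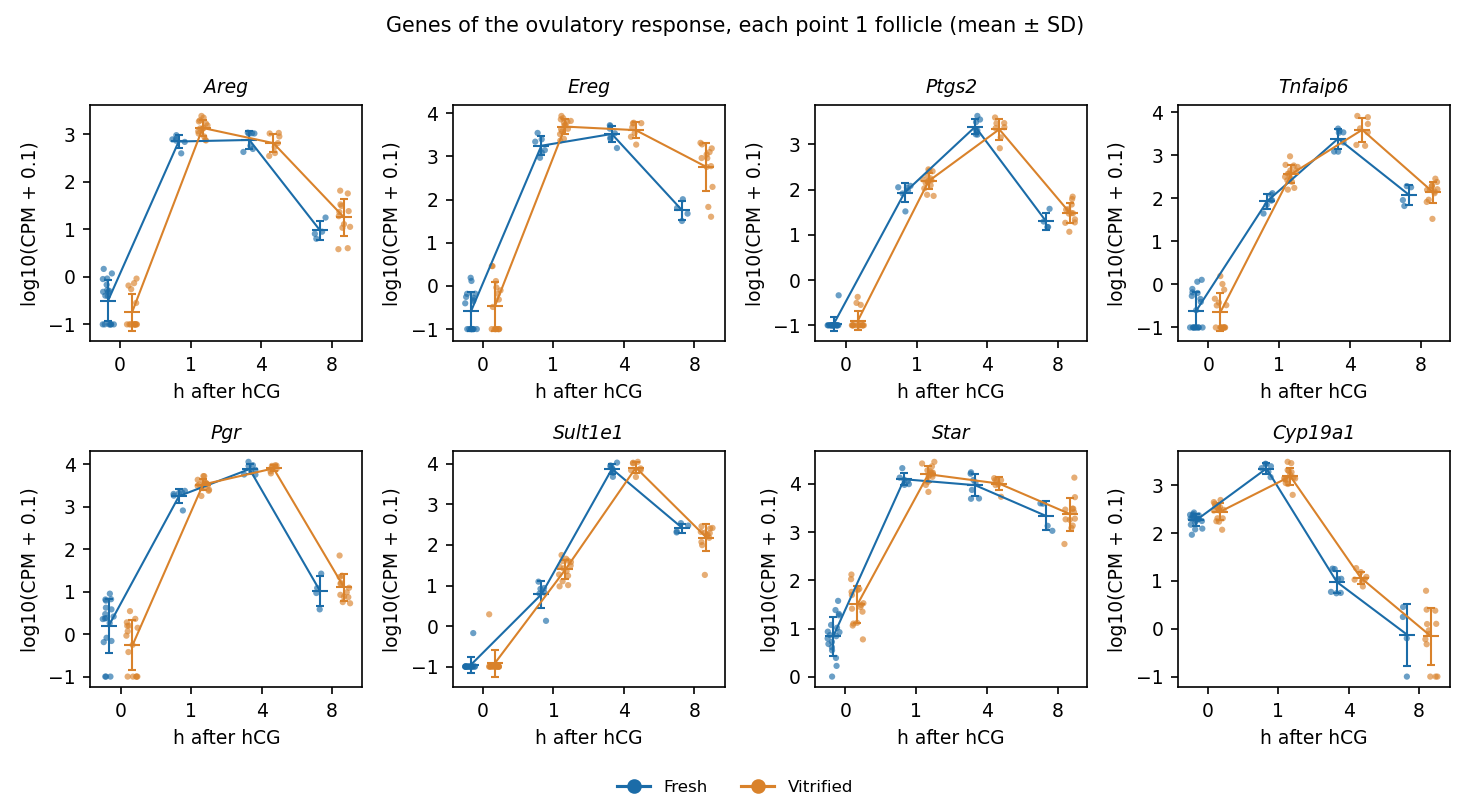
Abundance of 8 genes of the ovulatory response by hours after hCG (x axis) as log10(CPM + 0.1) (y axis), each point 1 follicle, fresh and vitrified in different colours, with lines through the means ± SD of the log values. Areg rose from 0.381 to 733 CPM in fresh and from 0.177 to 1460 CPM in vitrified follicles by 1 h, and Cyp19a1 dropped below 20 CPM in each follicle by 4 h.

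Between 1 h and 4 h genes of estradiol synthesis fell in fresh follicles and a second wave of genes rose. Cyp19a1 fell from 2300 ± 525 CPM (SD, n = 6) to 10.6 ± 5.48 CPM (n = 7), a log2 fold change of -7.76 ± 0.42 (SE; edgeR adjusted p = 3.07e-27). Fshr, the FSH receptor, changed by -6.91 ± 0.51 and Inhbb, an inhibin and activin subunit, by -6.64 ± 0.54. Sult1e1, a sulfotransferase that inactivates estrogens, rose from 7.17 ± 3.63 to 7750 ± 1970 CPM (10.11 ± 0.45, 1.14e-32). The neuropeptide Adcyap1 rose by 8.28 ± 0.90, the transcription factor Runx2 by 7.36 ± 0.42 and the EGF-like factor Btc by 6.56 ± 0.39. A total of 2552 genes rose and 2850 fell.

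None of 17 estradiol and FSH-dependent genes rose and 14 fell in fresh follicles over this interval (camera adjusted p = 4.72e-14), among them Nr5a2 (-4.41 ± 0.21) and Hsd17b1 (-5.90 ± 0.43). Granulosa markers, several of them also on that list, fell in 9 of 11 (4.53e-09). Cumulus and preantral genes fell in 8 of 12 (7.7e-05), including Nppc and Npr2, the ligand and receptor that hold the oocyte in meiotic arrest (-6.03 ± 0.47 and -2.98 ± 0.25). Cholesterol synthesis fell in 19 of 20 genes with a median of -1.72 (1.93e-09, adjusted p = 0.132 with an estimated correlation), for example Mvk at -3.86 ± 0.40 and Idi1 at -2.64 ± 0.27. Immediate early genes fell in 16 and rose in 1 of 24 (1.49e-06, adjusted p = 0.23 with an estimated correlation), with Nr4a2 at -8.83 ± 0.47. Endoplasmic reticulum stress genes fell in 12 and rose in 1 of 15 (0.000129), with Herpud1 at -4.81 ± 0.25 and Asns, asparagine synthetase, at 3.93 ± 0.34. Of 16 p53 targets 9 fell (0.0137). Cumulus expansion continued upward, 6 higher and 2 lower of 11 (0.0173), with Ptgs2 at 4.82 ± 0.33, the matrix proteoglycan Vcan at 3.32 ± 0.27 and Ptges, a prostaglandin E synthase, at -3.94 ± 0.31. Ovulatory transcription factors had 8 higher and 3 lower of 15 (0.00265).

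Lists that did not pass in fresh follicles over this interval included oxidative stress (2 higher and 9 lower of 17, camera adjusted p = 0.0799), heat shock (6 and 7 of 15, 0.499), proteases (6 and 4 of 16, 0.977), progesterone synthesis (3 and 6 of 15, 0.718), and theca and stroma markers (5 lower of 14, 0.164). Adjusted over the list alone, counts were the same except for 7 higher cumulus expansion genes, 9 higher ovulatory transcription factors, 1 higher p53 target, 4 higher and 7 lower progesterone genes and 4 lower theca and stroma markers.

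In vitrified follicles the same interval raised 2589 genes and lowered 3091 (limma on log2(TPM + 1): 2198 and 1290). Sult1e1 rose from 28.3 ± 14.3 CPM (n = 14) to 8390 ± 2400 CPM (n = 7), a log2 fold change of 8.84 ± 0.38 (edgeR adjusted p = 8.06e-34), Runx2 rose by 7.61 ± 0.37 and the adhesion molecule Alcam by 7.10 ± 0.41. Cyp19a1 changed by -7.79 ± 0.43, Inhbb by -7.15 ± 0.56 and Gadd45b by -6.56 ± 0.44. Estradiol genes fell in 16 of 17 (camera adjusted p = 5.72e-14), granulosa markers in 10 of 11 (6.74e-09), cumulus and preantral genes in 7 of 12 (5.2e-05), and cholesterol synthesis in 18 of 20 with a median of -1.66 (9.31e-08, adjusted p = 0.216 with an estimated correlation). Immediate early genes had 1 higher and 20 lower of 24 (7.53e-07, adjusted p = 0.209 with an estimated correlation), endoplasmic reticulum stress genes 1 and 12 of 15 (0.000101), p53 targets 1 and 9 of 16 (0.0157), and oxidative stress genes 1 and 10 of 17 (0.0181, adjusted p = 0.23 with an estimated correlation, 0.0503 without the vitrified-only plate). Cumulus expansion had 6 higher and 2 lower of 11 (0.0447, adjusted p = 0.0705 with an estimated correlation, 0.113 without the vitrified-only plate) and ovulatory transcription factors 9 and 4 of 15 (0.00138). Adjusted over the list alone, the differences were 19 lower cholesterol genes, 11 lower oxidative stress genes and 10 higher ovulatory transcription factors.

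Of the 5402 genes called in fresh follicles from 1 h to 4 h, 98.4% (98.1 to 98.8) had the same direction in vitrified follicles. Higher in both were 1999 (573.5 for independent lists) and lower in both 2373 (764.6), with 3 opposite, and across genes r was 0.868 (rho 0.856). The steps differed in 4 genes, with 795 at an unadjusted p under 0.05. Nfkbia rose by 1.48 in fresh and 2.92 in vitrified follicles (difference 1.44 ± 0.31, edgeR adjusted p = 0.0376). Hnrnpu had steps of 0.71 and -2.47 (difference -3.18 ± 0.67, 0.0376). Sos2, an exchange factor for Ras, had steps of 3.65 and -3.50 (difference -7.16 ± 1.45, 0.0376). Eif3b, a translation initiation factor named after its values were seen, had steps of 1.13 and -2.20 (difference -3.33 ± 0.73, 0.0482). Without the vitrified-only plate the adjusted p-values of Nfkbia, Hnrnpu, Sos2 and Eif3b were 0.0184, 0.0117, 0.0052 and 0.0184. None of the 4 was called with no low-count filter, with vitrified 4 h replicates 1 and 2 merged, or in a fit of the compared groups only (edgeR, 1741, 742 and 493 genes at an unadjusted p under 0.05), while the DESeq2 Wald test called 6 genes and limma 1. Random splits could not test the 4 calls. They were made in fits of the compared groups only, where the real split called 0 genes and others up to 8. Chance therefore stays open for these calls. Glycolysis was lower in this difference by camera (0.0252, adjusted p = 0.803 with an estimated correlation, 0.79 without the vitrified-only plate) with no member called, and it turned higher without a plate term (0.378).

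Over the last interval Pgr fell in fresh follicles from 7930 ± 2140 CPM (SD, n = 7) at 4 h to 12.9 ± 9.71 CPM (n = 4) at 8 h, a log2 fold change of -9.34 ± 0.77 (SE; edgeR adjusted p = 1.25e-16). Ptgs2 fell from 2600 ± 1020 to 21.6 ± 10.7 CPM (-6.90 ± 0.44), Areg from 817 ± 301 to 10.2 ± 5.09 CPM (-6.38 ± 0.58) and Ereg from 3550 ± 1380 to 60.9 ± 30 CPM (-5.88 ± 0.60). Susd3 rose by 7.16 ± 0.47, Tsc22d3, which glucocorticoids and progestins induce, by 6.99 ± 0.38, the secreted phosphoprotein Spp1 by 6.34 ± 0.60 and the vasoactive peptide gene Adm by 6.61 ± 0.89. Fshr rose again, by 5.24 ± 0.54, to 32.1 ± 7.24 CPM. Genes that rose numbered 2406 and those that fell 1835.

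EGF-like factors fell in 6 and rose in 1 of 15 in fresh follicles at this step (camera adjusted p = 0.000101), and cumulus expansion genes in 6 and 1 of 11 (0.00224), with Tnfaip6 at -4.36 ± 0.49 and Has2 at -3.13 ± 0.60. Granulosa markers fell in 5 and rose in 2 of 11 (0.00024, adjusted p = 0.0669 with an estimated correlation), with Inhba at -4.95 ± 0.27 and the gap junction gene Gja1 at -3.45 ± 0.30. Estradiol genes had 4 higher and 7 lower of 17 (0.00775, adjusted p = 0.272 with an estimated correlation) and cumulus and preantral genes 1 and 6 of 12 (0.0129). Immediate early genes fell in 8 of 24 (0.015, adjusted p = 0.733 with an estimated correlation). Endoplasmic reticulum stress genes fell in 5 of 15 (0.0159, adjusted p = 0.302 with an estimated correlation), and their median turned from -0.30 to 0.34 with total counts alone. Among lists that did not pass, cholesterol synthesis had 8 higher and 4 lower of 20 (0.644), with Mvk at 2.76 ± 0.43 and Lss at 1.70 ± 0.27. Heat shock had 3 and 6 of 15 (0.397), with the small heat shock protein Hspb1 at 4.91 ± 0.62. Ovulatory transcription factors had 6 and 6 of 15 (0.497), with Zbtb16 at 4.26 ± 0.42. Adjusted over the list alone, counts were the same except for 7 lower cumulus expansion genes, 6 lower granulosa markers, 8 lower estradiol genes, 5 lower cholesterol genes, 4 higher heat shock genes and 7 lower ovulatory transcription factors. Fresh follicles at 8 h numbered only 4, and scaling moved the division to 4979 higher and 697 lower with total counts alone and to 3332 and 382 with limma on log2(TPM + 1).

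Vitrified follicles from 4 h to 8 h raised 2899 genes and lowered 1863 (total counts alone: 5318 and 757; limma on log2(TPM + 1): 3359 and 490). Pgr fell from 8090 ± 1300 CPM (n = 7) to 16.9 ± 18 CPM (n = 12), a log2 fold change of -8.67 ± 0.55 (edgeR adjusted p = 9.27e-23), and Ptgs2, F3 and Sult1e1 changed by -6.59 ± 0.34, -6.36 ± 0.38 and -6.14 ± 0.34. Susd3 rose by 7.64 ± 0.47, Spp1 by 7.53 ± 0.65 and Hspb1 by 6.12 ± 0.57. EGF-like factors had 1 higher and 6 lower of 15 (camera adjusted p = 9.17e-06), cumulus expansion genes 1 and 6 of 11 (0.000206), granulosa markers 2 and 5 of 11 (7.92e-05), cumulus and preantral genes 1 and 7 of 12 (0.00869), and estradiol genes 4 and 7 of 17 (0.00568, adjusted p = 0.249 with an estimated correlation). Immediate early genes had 1 and 8 of 24 (0.0346, adjusted p = 0.781 with an estimated correlation, 0.173 without the vitrified-only plate). Endoplasmic reticulum stress genes had 1 and 6 of 15 (0.0159, adjusted p = 0.302 with an estimated correlation), with a median that turned from -0.32 to 0.35 with total counts alone. Adjusted over the list alone, cumulus expansion had 7 lower genes, cumulus and preantral genes 2 higher and immediate early genes 6 lower, and the other counts in this paragraph were the same.

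Of the 4241 genes called in fresh follicles from 4 h to 8 h, 97.6% (97.1 to 98) had the same direction in vitrified follicles. Higher in both were 1913 (605.4 for independent lists) and lower in both 1289 (296.7), with 7 opposite, and across genes r was 0.808 (rho 0.795). The steps differed in 7 genes, all lower in vitrified (829 at an unadjusted p under 0.05). This count depended on the setting: 96 without the vitrified-only plate (95 lower), 167 in a fit of the compared groups only (159 lower), 173 without a plate term (74 lower), 43 by the DESeq2 Wald test (29 lower) and 54 by limma (52 lower). Psme3, a proteasome activator, had steps of 1.14 in fresh and -1.86 in vitrified follicles (difference -3.00 ± 0.61, edgeR adjusted p = 0.0137), and Rad23b, which carries ubiquitinated proteins to the proteasome, 0.92 and -1.58 (difference -2.50 ± 0.54, 0.0263). Vapb, a membrane protein of the endoplasmic reticulum, had 0.63 and -1.46 (difference -2.09 ± 0.33, 0.000115). Among the others were Spred2 (difference -2.23 ± 0.43), Gnb2 (-1.96 ± 0.37) and Arf5 (-1.0 ± 0.22). Without the vitrified-only plate the adjusted p was 0.00736 for Psme3 and Rad23b and 0.00163 for Vapb. Fresh 4 h and fresh 8 h libraries of the shared plate repeat 3 sample numbers, so the fresh step may span different runs. Oxidative stress genes were lower in this difference by camera (0.0407, adjusted p = 0.302 with an estimated correlation, 0.687 without the vitrified-only plate) with no member called.

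**Figure D3:**
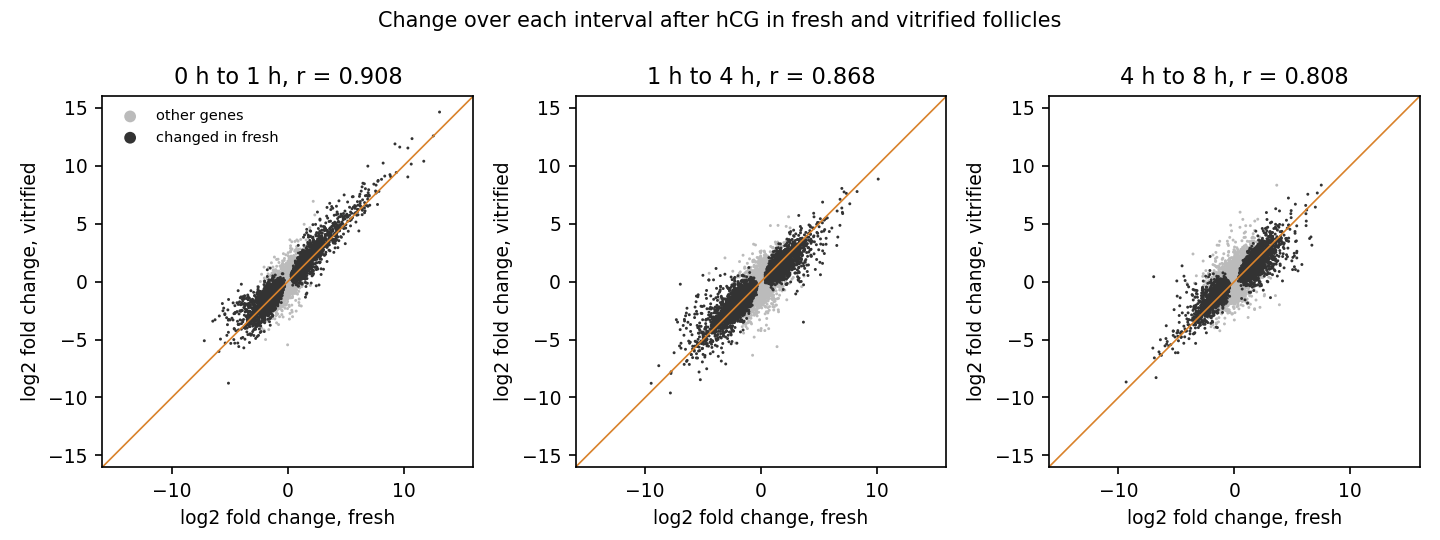
Log2 fold change of each gene in fresh (x axis) against vitrified follicles (y axis) for the steps from 0 h to 1 h, 1 h to 4 h and 4 h to 8 h, each point 1 gene, black where it changed in fresh follicles and grey otherwise, with a line where both are equal. Points follow the line in each panel, with r across genes of 0.908, 0.868 and 0.808.

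At 0 h, before hCG, vitrified follicles differed from fresh ones in 100 genes, 58 higher and 42 lower (n = 15 and 18). Sfrp4, a secreted modulator of Wnt signalling on chromosome 13 (19623104 to 19632994), was at 50.8 ± 47.2 CPM (SD) in vitrified and 5.76 ± 9.88 CPM in fresh follicles, 9.38-fold higher (log2 fold change 3.23 ± 0.55 SE, edgeR adjusted p = 0.000134). Kitl, the ligand of the oocyte receptor KIT on chromosome 10 (100015630 to 100100416), was 6.22-fold higher (22.9 ± 13.1 against 3.95 ± 3.08 CPM, 3.29e-06). Star was 4.38-fold higher (43.8 ± 36.3 against 10.1 ± 9.43 CPM, 0.000134) and the cell cycle inhibitor Cdkn1a 2.71-fold higher (log2 fold change 1.44 ± 0.20, 2.79e-06). Lower in vitrified follicles were Igfbp3, which binds insulin-like growth factors (log2 fold change -2.50 ± 0.67, 0.0432), the serpin Serpina3a (-1.71 ± 0.31, 0.000469), the scaffold protein Ahnak (-1.43 ± 0.26, 0.000312), the procollagen protease Bmp1 (-1.03 ± 0.23, 0.00735) and Myc (-0.96 ± 0.24, 0.0271).

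Genes of the FSH response were higher in vitrified follicles at 0 h for Fshr at 160 ± 59.7 against 82.4 ± 28.1 CPM (log2 fold change 0.96 ± 0.21, edgeR adjusted p = 0.00567) and Inha at 0.39 ± 0.09, while Grb14 stood at -0.59 ± 0.16. As a list estradiol genes did not pass camera (2 higher and 1 lower of 17, adjusted p = 0.298; 3 higher adjusted over the list alone). The p53 targets Cdkn1a, Trp53inp1 (0.82 ± 0.19) and Sesn2 (0.69 ± 0.18) were higher, 3 of 16, with the list at 0.139 (4 higher and 1 lower adjusted over the list alone). Cholesterol synthesis was higher as a list (0.00024, adjusted p = 0.507 with an estimated correlation), with only Srebf2, the regulator of the pathway, called (0.35 ± 0.10; 3 higher adjusted over the list alone). Progesterone synthesis was higher as well (0.0169, adjusted p = 0.318 with an estimated correlation), with Star and Fdx1 (0.61 ± 0.17) called of 15. With limma on log2(TPM + 1) the medians of both lists lay below 0.

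Markers of other cell types also differed at 0 h. Theca and stroma markers held 0.318% ± 0.144 of counts (SD, n = 15) in vitrified and 0.241% ± 0.117 (n = 18) in fresh follicles, while the median log2 fold change of the list was -0.84 (camera adjusted p = 0.0129, adjusted p = 0.579 with an estimated correlation). Against that direction Aldh1a1, the 1 called member of 14, was higher by 1.67 ± 0.38; adjusted over the list alone 2 were higher and 6 lower. Endothelial markers had a median of -0.98 (0.00408, adjusted p = 0.348 with an estimated correlation) and none of 6 called. Their counts were very low, with 0.00321% ± 0.00203 of counts (SD) in fresh and 0.00168% ± 0.00156 in vitrified follicles. Heat shock genes (none of 15 called, camera adjusted p = 0.915), oxidative stress (none of 17, 0.904), endoplasmic reticulum stress (1 higher of 15, 0.762), inflammatory genes (none of 7, 0.81), immediate early genes (1 lower of 24, 0.187) and oocyte markers (none of 18, 0.62) did not pass.

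Some of the called genes have near-identical copies whose reads the counting may have divided, so their values are uncertain. Rps3a3, a processed pseudogene of a ribosomal protein gene on chromosome 13 (108670603 to 108671397), was at 561 ± 224 CPM in vitrified and 75.4 ± 33.1 CPM in fresh follicles (log2 fold change 2.89 ± 0.40, edgeR adjusted p = 2.79e-06). Rps2 differed by 1.80 ± 0.30, and the histocompatibility genes H2-K2, H2-Q1, H2-Q6 and H2-Q4 by -1.99 ± 0.30, -1.29 ± 0.24, -1.04 ± 0.24 and -0.96 ± 0.21. A further member of that family, H2-K1, went the other way (527 ± 213 against 292 ± 114 CPM, log2 fold change 0.86 ± 0.19, 0.0056). Scaling moved the division to 39 higher and 117 lower with total counts alone and to 27 and 1271 with limma on log2(TPM + 1). Without 7 libraries under 1500000 counts, 5 of them vitrified at 0 h, 61 genes were called.

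At 1 h vitrified minus fresh gave 45 higher and 10 lower genes (n = 14 and 6). Sfrp4 was again higher, 568 ± 398 against 59.6 ± 48.0 CPM (SD; log2 fold change 3.76 ± 0.87 SE, edgeR adjusted p = 0.0192), and Odc1, the first enzyme of polyamine synthesis, by 2.71 ± 0.62 (0.0192). The RNA-binding protein Hnrnpu was higher by 2.61 ± 0.50 (0.00263), and Tnfaip6 of the cumulus matrix was at 412 ± 208 against 91.4 ± 32.2 CPM (1.75 ± 0.37, 0.0114). Nfkbia was lower, 15.8 ± 5.29 against 47.8 ± 19.1 CPM (-1.32 ± 0.23, 0.000511), as was Ahnak (-1.62 ± 0.39, 0.0264). The value for Ahnak depended on the plate term: its mean was 262 ± 164 CPM in fresh follicles, 97.1 ± 40.8 CPM in vitrified ones of the shared plate and 279 ± 153 CPM in those of the vitrified-only plate, and without the term the log2 fold change was -0.30 ± 0.40 (0.741). H2-K1, which shares sequence with other H2 genes, was at 700 ± 160 against 207 ± 82.6 CPM (1.90 ± 0.32, 0.000511).

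Among the induced genes, Areg had a log2 fold change of 0.83 ± 0.37 at 1 h (edgeR adjusted p = 0.365), Pgr of 1.16 ± 0.46 (0.279) and Kitl of 1.19 ± 0.51 (0.331), none of which passed. The median SE over all genes was 0.37, and the 95% interval lay within 2-fold for 45.5% of genes. Sult1e1 of the ovulatory list was higher, by 1.38 ± 0.35 (0.0419). Inflammatory genes were lower as a list (camera adjusted p = 0.00184), with Nfkbia called of 7, the same when adjusted over the list alone. These 7 were the tested part of a list of 21. Most of its cytokines and chemokines, among them Cxcl2, Ccl2, Il1b and Tnf, were not tested, so the result does not cover them. Glycolysis and hypoxia genes were higher (0.00115, adjusted p = 0.582 with an estimated correlation), with none of 18 called and 3 higher adjusted over the list alone. The adjusted p of glycolysis was 0.516 without the vitrified-only plate and that of inflammatory genes 0.00281, and without a plate term the glycolysis list turned lower (0.438). The immune marker Lyz2 had a log2 fold change of -2.56 ± 1.14 (edgeR adjusted p = 0.356), and immune markers held 0.00337% ± 0.00143 of counts (SD) in fresh and 0.000503% ± 0.00132 in vitrified follicles, which was not tested. Within the shared plate (n = 5 and 6) Odc1, Hnrnpu, H2-K1, Nfkbia and Tnfaip6 kept an adjusted p under 0.05 (0.00213, 0.00141, 0.00213, 0.00141 and 0.0442), while Sfrp4 (3.62 ± 0.96, 0.0624), Ahnak (-1.43 ± 0.45, 0.173) and Sult1e1 (1.04 ± 0.37, 0.249) no longer passed. Areg (0.743 ± 0.355, 0.459), Pgr (0.602 ± 0.459, 0.691) and Kitl (1.435 ± 0.53, 0.269) did not pass there either. The estimate for Pgr thus depended on the libraries used. Its mean was 1880 ± 549 CPM in fresh follicles. Vitrified ones had 2840 ± 732 CPM on the shared plate and 3810 ± 988 CPM on the vitrified-only plate. Without the vitrified-only plate 57 genes were higher and 4 lower, 38 of the 61 shared with the 55, and with total counts alone the division was 18 and 40, with limma on log2(TPM + 1) 5 and 21, and without a plate term 141 and 110. The fresh and vitrified 1 h rows of the shared plate repeat 4 sample numbers, so they may come from different runs. A fit of the 1 h libraries by themselves called 2 genes.

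At 4 h vitrified and fresh follicles (n = 7 and 7, all on the shared plate) differed in 13 genes, 8 higher and 5 lower, with 718 at an unadjusted p under 0.05. A fit of the 4 h libraries by themselves called 17, 8 higher and 9 lower, of which 5 were among the 13. Epdr1 was 4.43-fold higher in vitrified follicles (log2 fold change 2.15 ± 0.33, edgeR adjusted p = 5.62e-05). Zbtb16, a transcription factor that progestins induce, was at 10.1 ± 2.93 against 2.74 ± 1.61 CPM (1.81 ± 0.42, 0.0375), and the glutathione transferase Gstm2 was higher by 1.06 ± 0.23 (0.0191). Serpina3a (-2.72 ± 0.51, 0.00199), the phospholipid enzyme Agpat1 (-1.22 ± 0.21, 0.000346) and the transketolase Tkt (-0.99 ± 0.16, 0.000156) were lower. Igsf9b (1.83 ± 0.40, 0.0152) and the pseudogene Rps3a3 (3.18 ± 0.64, 0.00659) were higher.

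Cholesterol synthesis genes were higher as a list at 4 h, with a median of 0.39 and no member of 20 called (camera adjusted p = 2.08e-06, adjusted p = 0.302 with an estimated correlation). Progesterone synthesis was higher too (0.0384, adjusted p = 0.426 with an estimated correlation), with none of 15 called and 3 higher adjusted over the list alone, but its median turned from 0.04 to -0.02 with total counts alone. Endothelial markers were lower, with a median of -1.62 and none of 6 called (0.00772, adjusted p = 0.41 with an estimated correlation). Their counts were very low: the list held 0.0021% ± 0.00226 of counts (SD) in fresh and 0.000941% ± 0.000694 in vitrified follicles. Sfrp4 was at 6010 ± 2140 CPM in vitrified and 690 ± 1510 CPM in fresh follicles, where replicate 7 had 4115 CPM and the others 79.2 to 217 (log2 fold change 3.12, edgeR adjusted p = 0.0758). With vitrified replicates 1 and 2 merged 8 genes were called.

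At 8 h 121 genes differed, 54 higher and 67 lower in vitrified follicles (n = 12 and 4). Ptx3, a pentraxin that cross-links the cumulus matrix, on chromosome 3 (66219910 to 66225805), was at 15.6 ± 14.1 CPM in vitrified and 299 ± 302 CPM in fresh follicles (SD), where the follicles ranged from 1.43 to 44.3 and from 107 to 748 CPM (log2 fold change -4.37 ± 0.80 SE, edgeR adjusted p = 0.0011). Also lower were the nucleic acid-binding protein Ybx1 (-2.77 ± 0.67, 0.0201), the nucleoporin gene Ahctf1 (-2.71 ± 0.52, 0.00164), Psme3 (-2.48 ± 0.48, 0.00144) and Rad23b (-2.38 ± 0.41, 0.000224). Rbm3, a cold-inducible RNA-binding protein, changed by -1.12 ± 0.19 (0.000224). Higher in vitrified follicles were Net1, an exchange factor for RhoA (2.08 ± 0.39, 0.000981), the Cdc42 effector Cdc42ep5 (1.63 ± 0.33, 0.00218) and Ereg (2.36 ± 0.55, 0.0135).

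Cholesterol synthesis was higher as a list at 8 h (camera adjusted p = 0.00374, adjusted p = 0.665 with an estimated correlation), with a median of 0.47 and only Srebf2 called of 20 (0.75 ± 0.18; 3 higher adjusted over the list alone). Oxidative stress genes were lower (0.0299, adjusted p = 0.3 with an estimated correlation), with none of 17 called and 2 lower adjusted over the list alone. Within the shared plate (n = 3 and 4) 221 genes were called, 31 higher and 190 lower, 63 of them among the 121, and neither list call was kept. There Ptx3 (-5.99, adjusted p = 0.000276), Net1 (1.76, 0.00578), Cdc42ep5 (1.64, 0.00396), Rbm3 (-1.01, 0.0126), Psme3 (0.00301) and Rad23b (0.000706) stayed past the threshold, whereas Ereg (0.75 ± 0.49, 0.633), Cnnm2 (0.44 ± 0.50, 0.914, from 2.50 ± 0.53 over both plates) and Srebf2 (0.70 ± 0.22, 0.0727) did not. Ereg lay between 569 and 2050 CPM in the vitrified-only plate, and the vitrified follicles of the shared plate had from 39.8 to 196 CPM, near the 31.8 to 101 CPM of fresh follicles. Fresh 8 h libraries repeat 3 sample numbers of fresh 4 h libraries, so whether fresh and vitrified 8 h libraries of the shared plate had a run in common is unknown. Leaving out fresh replicate 1, 2, 3 or 4 gave 45, 59, 64 or 77 genes. The division over both plates depended on the setting: 474 higher and 252 lower without a plate term, 162 and 127 by the DESeq2 Wald test, 27 and 94 with total counts alone, 32 and 122 with limma on log2(TPM + 1), and 51 and 229 in a fit of the 8 h libraries by themselves.

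Calls of vitrified minus fresh were compared between times. The sets of 0 h and 1 h shared 7 genes (0.477 for independent lists), namely Ahnak, Ddr1, H2-K1, Nr3c2, Rps2, Rps3a3 and Sfrp4, each with the same direction. The sets of 0 h and 4 h shared 4 (0.113), including Serpina3a, Agpat1 and Rps3a3, and those of 0 h and 8 h shared 2 (1.05), H2-K2 and Srebf2. Of the genes shared with 0 h, Ddr1, H2-K1, Agpat1 and H2-K2 lie in the H2 region of chromosome 17 (33974659 to 37274484). Rps2 and Rps3a3 have near-identical copies. For genes of that region, donor variants and a lasting effect of vitrification cannot be told apart, since the labels name no donors. Rps3a3 was shared by 1 h and 4 h (0.0621 for independent lists), Net1 by 1 h and 8 h (0.578) and Epdr1 by 4 h and 8 h (0.137). At 8 h Rps3a3 had a log2 fold change of 2.64 ± 0.80 (0.0822), short of the threshold. A gene missing from a set may still differ, since at most 68.7% of simulated 2-fold changes were recovered in these comparisons. Of the 100 genes of 0 h, 86 had the same sign at 1 h, 86 at 4 h and 78 at 8 h. Sfrp4 at 8 h was at 1870 ± 1140 CPM (SD, n = 12) against 234 ± 202 CPM (n = 4), with a log2 fold change of 3.54 ± 1.02 (SE; edgeR adjusted p = 0.0613).

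**Figure D4:**
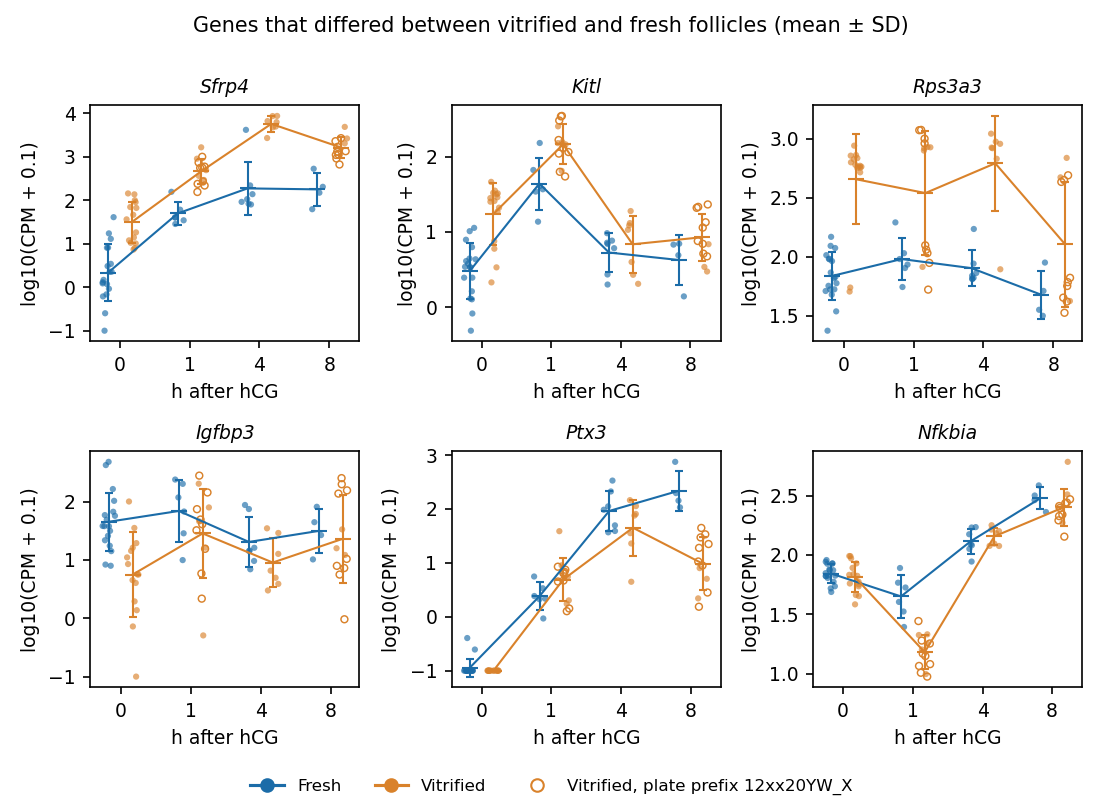
Abundance of Sfrp4, Kitl, Rps3a3, Igfbp3, Ptx3 and Nfkbia by hours after hCG (x axis) as log10(CPM + 0.1) (y axis), each point 1 follicle, fresh and vitrified in different colours, open symbols for the vitrified-only plate, lines through means ± SD of the log values. Sfrp4 was at 50.8 against 5.76 CPM in vitrified and fresh follicles at 0 h, and Ptx3 at 15.6 against 299 CPM at 8 h.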

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

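The tests of shared reads, of the gap between Rps3a3 levels, of the Rps3a3 range in fresh follicles and of the theca genes Cyp17a1 and Insl3 were chosen only after the result was seen. For the theca genes, the requirement that each also pass edgeR's threshold was added after their permutation p was known, and for the Rps3a3 range the requirement that it hold at 0 h as well was added after the shares were known. Without these additions both explanations would have been argued against outright. The test of stroma was first set by the correlation of its markers alone, which counted in its favour; that their share of counts be lower too was required only after it was known to be higher.

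The first pattern is the concentration of 0 h calls in the H2 region of chromosome 17 (33974659 to 37274484) and in Rps3a3. Of 84 tested genes of the region 10 differed between vitrified and fresh follicles (11.9%), 4 higher and 6 lower, against 90 of 11437 elsewhere (0.787%; Fisher's exact p = 2.49e-09). Reads shared between similar genes are argued against as the whole cause, since 5 of the 67 region genes outside the H2 family were called too (Fisher's exact p = 0.000223). Whether Rps3a3 rose in each vitrified follicle stays open, since the bound set against it had to be passed over all times and at 0 h. Over all times 33.3% of vitrified libraries (16 of 48, 95% interval 20.4 to 48.4) lay inside the range of the fresh ones. At 0 h 13.3% did (2 of 15, 1.66 to 40.5). The range pools fresh libraries of all times, so a small rise inside it would not be seen. Variants that differ between donors of this outbred strain may underlie the region, where 93.3% of gene and time pairs (28 of 30) kept the 0 h direction at later times, compared with 82.2% (222 of 270) for genes called elsewhere. A lasting effect of vitrification would keep the direction too, so this share cannot tell donor variants from vitrification. For Rps3a3 a variant carried by some donors is a candidate explanation, since vitrified libraries fell into 16 at 33.3 to 124.6 CPM and 32 at 430.1 to 1188 CPM, a gap of 1.79 log2 units, but an effect of vitrification on the H2 region stays open because the labels do not name donors.

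The second pattern is a split of the vitrified 8 h follicles by plate, with 2725 of 10163 genes called between the 9 libraries of the vitrified-only plate and the 3 of the shared plate (edgeR), 1335 higher and 1390 lower, where the same comparison at 1 h called 1 of 6904. A technical difference that acts alike at both times is argued against, as the plate differences at 8 h and 1 h correlated across genes at r = 0.137 (rho 0.174). Library depth as the main cause is argued against as well: 77.4% of 2708 genes were still called after all libraries were thinned to 1908953 counts. Whether the vitrified-only follicles stood at an earlier point of the response cannot be told apart from other differences between plates, since the plate difference correlated with the fresh step from 4 h to 8 h at r = -0.135 (rho -0.204), between the bounds set for and against, and the labels give neither donors nor culture runs. Apart from that, no biological explanation was tested.

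The third pattern is that 11 of 14 theca and stroma markers had a log2 fold change below 0 in vitrified follicles at 0 h, with a list median of -0.84, although the share of counts in the list was higher (0.318% ± 0.144 against 0.241% ± 0.117 in fresh, SD). Total counts alone could not test scaling in general, since they moved the median of all genes at 0 h only from -0.016 to -0.129. The list median was -0.91 (-0.912) there, so the choice between TMM and total counts did not account for it. Less theca of every kind stays open: Cyp17a1 and Insl3, of steroid-producing theca cells, averaged 1.49 log2 units more in vitrified follicles (permutation p = 0.00355), but they were picked among members that went against the list, and neither passed edgeR's test (adjusted p = 0.352 and 0.451). Less attached stroma stays open as well: the 11 lower markers (among them Col1a1, Col3a1 and Dcn) moved together from follicle to follicle with a median correlation of 0.624, but they were picked for being lower, and markers of one cell type would move together in any case. How follicles were isolated and picked was not compared here, and an effect of vitrification on stromal cells stays open.

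Single follicles stood apart from the rest of their group in 14 of 100 tested sets of values, where chance alone gives about 1 in 20, or 5. At 1 h, fresh replicate 1 had 815.9 CPM of Pgr (others 1825 to 2363). Fresh replicate 2 at that time had 21250 CPM of Star (9558 to 13540), and fresh replicate 3 had 155.1 CPM of Sfrp4 (28.21 to 60.11) and 195 CPM of Rps3a3 (55.14 to 106.8). At 4 h, fresh replicate 4 had 0.192% of counts in theca and stroma markers (0.02078 to 0.09099) and 171.5 CPM of Rps3a3 (64.29 to 87.14), and fresh replicate 7 had 4115 CPM of Sfrp4 (79.23 to 217.3). Among vitrified follicles of 4 h, replicate 6 had 0.07758% in oocyte markers (0.04602 to 0.0593) and 8.793 CPM of Fshr (0.5412 to 2.587). Vitrified replicate 4 had 0.09415% in theca and stroma markers (0.02476 to 0.05284), and vitrified replicate 7 had 78 CPM of Rps3a3 (675.9 to 1104). At 8 h, fresh replicate 1 held 34.09% of counts in its 50 most abundant genes (37.46 to 38.12) and 21.29 CPM of Fshr (34.92 to 36.82), and fresh replicate 4 had 747.9 CPM of Ptx3 (106.8 to 196.8).

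Steps of vitrified and fresh follicles differed by edgeR's test of the difference itself in 14 cases, among them the following, given as log2 vitrified minus fresh. From 0 h to 1 h there were Fam222b (1.59), Hnrnpu (2.85) and Nfkbia (-1.25), from 1 h to 4 h Eif3b (-3.33), Hnrnpu (-3.18), Nfkbia (1.44) and Sos2 (-7.16), and from 4 h to 8 h Arf5 (-1.003), Gnb2 (-1.96), Psme3 (-3.00), Rad23b (-2.50), Spred2 (-2.23) and Vapb (-2.09).

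Random splits of the same libraries were made in fits of the compared groups only. They bear on the counts of those fits, not on the calls of the main model. The main model called 100, 55, 13 and 121 genes for vitrified minus fresh at 0, 1, 4 and 8 h. For most counts of the split fits chance was excluded, taking follicles as independent, which the labels do not show. For vitrified minus fresh at 0 h the real split called 115 genes and the highest other 45, with 1 of 100 splits as large, the real one. At 4 h it was 17 against 9, 1 of 99. At 1 h the real split called 2 and 4 of 100 splits called as many, so that the share lay under 0.05, but the highest other called 18. At 8 h the real split called 280 and the highest other 357, with 2 of 95 as large. That other split set vitrified replicates 1 to 4 apart from all other 8 h libraries. These are the 3 of the shared plate and 1 of the vitrified-only plate, so it does not follow the plates. Within the shared plate it parts vitrified from fresh follicles, as the real grouping does, and 221 genes were called there. For the steps from 0 h to 1 h, 1 h to 4 h and 4 h to 8 h the real splits called 4262, 4102 and 4039 genes in fresh and 3723, 3987 and 4051 in vitrified follicles, the highest others 4, 0, 2, 1, 0 and 0, each with 1 of 25 as large. For the differences between steps chance was not excluded from 0 h to 1 h (real 4, highest other 64, 4 of 50 as large, which points to a structure among the libraries that was not tested). From 1 h to 4 h the splits could not test it, since the real split called 0 genes and 50 of 50 were bound to be as large (highest other 8). Chance was excluded from 4 h to 8 h (real 167, highest other 1, 1 of 50). The splits take no account of plates. Where vitrified libraries of 1 h or 8 h take part, a count beyond chance may therefore come from the vitrified-only plate. Without that plate the difference from 4 h to 8 h still called 96 genes. Fresh 4 h and fresh 8 h libraries repeat 3 sample numbers, though, so a difference between runs may enter that count.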

How the results depend on the processing

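Total counts alone, leaving out libraries under 1500000 counts, and merging vitrified 4 h replicates 1 and 2 were tests chosen after the results were seen. Of the named calls Gja1 (0.51 to -0.084) and Aldoa (0.46 to -0.156) of the vitrified step from 0 h to 1 h changed sign, with total counts alone. Of all calls, those that kept their direction with total counts alone numbered 4714 of 4878 (fresh) and 5371 of 5749 (vitrified) from 0 h to 1 h, and 4124 of 4241 and 4599 of 4762 from 4 h to 8 h. With limma, 2555 of 2841 and 2926 of 3193 tested calls from 4 h to 8 h did so. Calls kept in each alternative numbered 14 of 28 named genes at 0 h, 1 of 19 at 1 h, 4 of 8 at 4 h and 8 of 25 at 8 h for vitrified minus fresh. They were 77 of 82, 86 of 89 and 66 of 80 for the fresh steps, 75 of 87, 84 of 88 and 73 of 79 for the vitrified steps, and 0 of 3, 0 of 3 and 4 of 7 for the differences between steps. Where a reason is not stated, the cause was not tested. No paired analysis was possible because the labels carry no replicate numbers; those used here follow the order of the samples.

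The DESeq2 Wald test called 167 genes at 0 h (100 by edgeR), 115 at 1 h (55), 25 at 4 h (13) and 289 at 8 h (121). For differences between steps it called 22 from 0 h to 1 h (3) and 43 from 4 h to 8 h (7). limma on log2(TPM + 1) called 1298 at 0 h, 26 at 1 h, 3110 and 3337 in the fresh steps from 0 h to 1 h and 1 h to 4 h, and 3320 and 3488 in the vitrified ones, on fewer genes. It called 0, 1 and 54 in the 3 differences. Where it called 0, 340 of 7244 genes had an unadjusted p under 0.05, no more than the 1 in 20 that chance alone gives.

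Without a plate term the counts were 251 at 1 h, 726 at 8 h and 21 and 173 for the differences from 0 h to 1 h and 4 h to 8 h. Without the vitrified-only plate they were 221 at 8 h (63 shared with the 121), 7 and 96. Only the compared groups gave 2 at 1 h, 280 at 8 h, 3723 in the vitrified step from 0 h to 1 h, and 0 and 167 for the differences from 1 h to 4 h and 4 h to 8 h. No low-count filter gave 68 at 8 h and 6 and 0 for the first differences. Leaving out 1 fresh 8 h follicle gave 45 to 77 at 8 h (replicate 1 to 4: 45, 59, 64, 77) and 5 to 9 for the difference from 0 h to 1 h (9, 7, 5, 9). Total counts alone gave 156 at 0 h and 2 for the difference from 1 h to 4 h. Without libraries under 1500000 counts there were 61 at 0 h (48 shared), and 10 and 11 for the differences from 0 h to 1 h and 4 h to 8 h. With vitrified 4 h replicates 1 and 2 merged there were 8 at 4 h and 0 for the difference from 1 h to 4 h. Behind the 3 edgeR counts of 0 from 1 h to 4 h lay 1741 of 21572 (no filter), 742 of 11538 (merged) and 493 of 8218 (compared groups) genes at an unadjusted p under 0.05. About 1 in 20 would be there by chance alone. The DESeq2 Wald test called 6.

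The share of fresh calls with the same direction in vitrified follicles moved beyond its interval to 96.85% (no filter), 99.14% (total counts alone) and 98.29% (without libraries under 1500000 counts) from 0 h to 1 h. From 1 h to 4 h it moved to 96.91% (no filter), 98.03% (no plate term) and 97.45% (limma), and from 4 h to 8 h to 95.67% (no filter), 95.3% (no plate term), 96.23% (without the vitrified-only plate), 96.98% (limma) and 95.03% (compared groups). Over all genes vitrification took 2.423% of the variance (p = 0.113, permutation). Within the shared plate the 1 h difference in the top-50 share was 2.7056 points, no longer past the threshold, and in total counts 2012500, newly past it. Gene list calls went from 71 to 37 with an estimated correlation. Depth and group size limit what was seen: the 95% interval lay within 2-fold for 78.8% of genes at 0 h, 45.5% at 1 h, 48.9% at 4 h and 37.4% at 8 h.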

Other observations

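The tests in this part on Rps3a3 and on the plates of Ereg were chosen only after the result was seen. Rps3a3, a processed pseudogene, lay above the gap between its levels in 13 of 15 vitrified libraries at 0 h, 8 of 14 at 1 h, 6 of 7 at 4 h and 5 of 12 at 8 h, and in no fresh library (23.43 to 195 CPM in 35). The sum of Rps3a1, Rps3a2 and Rps3a3 was 2098 ± 424.3 CPM (SD, n = 15) in vitrified and 1462 ± 498.9 CPM (n = 18) in fresh follicles at 0 h.

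Ereg at 8 h had a mean of 1200 ± 531 CPM (SD, n = 9) in the vitrified-only plate and 101 ± 83.3 CPM (n = 3) in vitrified follicles of the shared plate. At 1 h the corresponding means of Ereg were 6180 ± 1570 CPM (n = 9) and 3530 ± 1220 CPM (n = 5).

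Gm10800, a predicted gene model, held 7.18% ± 2.15 of counts (n = 18) in fresh and 9.79% ± 4.06 (n = 15) in vitrified follicles at 0 h (permutation test, adjusted p = 0.434). All 5 libraries of 0 h under 1500000 counts were vitrified follicles of a single plate row.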
